A study of Gallus gallus and Mus musculus with 4 samples.

How the data were processed

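The series holds 4 RNA-seq samples of cochleae collected on day 3 after the start of gentamicin, an aminoglycoside antibiotic that kills hair cells. There is 1 sample per group. The mouse pair comes from Kunming mice at postnatal day 0 to 1 and consists of a control sample and a gentamicin sample. The chicken pair, at postnatal day 6 to 8, consists of a saline control and a gentamicin sample and was not analysed here. Per the labels' protocols, cochleae were exposed for 2 days and kept for 1 day more, whole-mount cultures were pooled before RNA extraction, and polyadenylated RNA was fragmented, copied with random primers and sequenced on an Illumina HiSeq instrument. Per the labels, the mouse samples were treated in vitro and the chicken samples in vivo.

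The mouse table deposited by the authors has 1 line per transcript model, 70189 in all, with an identifier, a length in bases, a strand, a gene identifier and a locus. TopHat2, a spliced-read aligner, and Cufflinks, a transcript assembler, are named in the submitters' processing notes, with no role or version. The genome build and annotation release are not given in the sources used here. The table also has 4 columns of values per library. They name 2 libraries by codes that occur in none of the labels, so these columns cannot be tied to control or gentamicin by name. They were not used in any step, and column order or values were not used in place of a label. Depth per sample was therefore not analysed here.

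The comparison fixed before the data were examined was gentamicin against control in mouse, as log2 ratios of scaled counts per gene and per gene list. It needs those columns and was not run. What is reported is the authors' transcript catalogue, which is tied to no single library and says nothing about gentamicin. Only 35 gene lists and 17 gene names were fixed before the data were examined. The catalogue measures, their strata, tests and alternatives were chosen after the table had been seen, including the raw shares per list and their trends with gene span and number of annotated models.

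Models were sorted by identifier into annotated (Ensembl transcript identifiers), new models of Ensembl genes, models of new genes, and unnamed models. New means named so by the authors of the table. GENCODE M21 (assembly GRCm38) was used as reference annotation. Of the 21314 Ensembl genes found in M21, 99.97% lay on its chromosome and strand and 60.4% had exactly its start, and of the 47599 annotated models found in M21, 83.4% had exactly its length. Coordinates are those of the table, except for genes listed under another gene's identifier and for overlap with reference genes, which use M21. Symbols came from a reference table of Ensembl identifiers and matched 21237 of 21674 Ensembl genes. Of the 926 distinct genes on the lists, 901 were matched.

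A gene was scored by whether it had at least 1 new model, over 21665 genes with at least 1 annotated model. The 9 genes without one were left out. Long genes and genes with many annotated models had new models more often, so each list was compared with genes of the same number of annotated models (1, 2, 3, 4, or 5 and more) and the same one of 5 bins of gene span. Span was that of the table's locus, which new models may have lengthened. Matching on it may therefore remove part of an excess. The matching covered neither expression nor number of exons. Genes therefore count toward an expectation whatever their expression in the cochlea. The test is a two-sided exact test whose null distribution combines 1 hypergeometric distribution per stratum, with Benjamini-Hochberg adjustment over the 35 lists and a threshold of 0.05. Genes are not independent replicates, and the p-values describe this catalogue, not animals or treatments. Shares have exact Clopper-Pearson 95% intervals, which cover sampling of genes only. Tested on simulated lists of 30 genes among the 21665 genes, 300 lists per size, the unadjusted test called 4% of lists at an odds ratio of 1, 31% at 2, 81.3% at 4 and 97.7% at 8.

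New genes were compared with M21 genes by overlap of at least 1 base on the same strand, and with 1000 sets of the same intervals shifted by 100 kb to 1 Mb to places free of same-strand Ensembl genes of the table. An Ensembl gene identifier holding annotated models that M21 assigns to a gene of another symbol was called a joined locus. Named genes are the 17 fixed names, the 12 genes with the most new models outside joined loci, without predicted genes, and up to 4 members per list with the most new models. The parts of the naming rule that used log2 ratios could not be applied, and the parts by number of new models were added after the table was seen. Not every gene that the rule names is reported here. Non-coding genes and a few other single genes were picked from the results. Alternatives left out joined loci or sequences outside the main chromosomes, asked for at least 2 new models or a new model longer than any annotated one, counted the unnamed models, used Fisher's exact test without strata, 10 span bins, strata of annotated length, or the genes of the other lists as background, and required the reference gene to cover the larger part of the new gene. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.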

Results

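The study sequenced polyadenylated RNA from mouse and chicken cochleae on day 3 after the start of gentamicin or control treatment, with 1 pooled sample per group, to follow the transcriptome after loss of hair cells, the mechanosensory cells of the inner ear. The values per library of the mouse table could not be tied to a treatment by name and were not used, so no difference between gentamicin and control is reported. The measurements below describe which transcripts the authors' mouse catalogue lists without an Ensembl transcript identifier. The new models of Ensembl genes were not compared with M21 transcripts, so some may already be annotated there. There are no replicates of this catalogue, and depth per sample was not analysed here.

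The mouse catalogue held 70189 transcript models. Annotated Ensembl transcripts made up 48525 of them (69.1%), with a median length of 1854 bases. Another 21064 models were new models of Ensembl genes and had a median length of 3682 bases. The annotated median also covers genes without a new model, so these medians do not compare models of the same genes. A further 586 models belonged to 412 genes that the authors named as new, with a median length of 1356 bases, and 14 models had no such name. Of the annotated transcripts found in GENCODE M21, 97.9% were classed there as protein-coding.

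At least 1 new model was listed for 10139 of 21665 genes (46.8%, 95% exact interval 46.1 to 47.5%). A single new model was listed for 4940 genes, 4 or more for 1335 and 10 or more for 58. The longest new model exceeded the longest annotated one in 5775 genes, 57.0% of those with a new model, by a median of 255 bases (quartiles 96.5 and 754). The share was 22.4% among genes with 1 annotated model, 52.8% with 2 and 96.6% with 5 or more. It was 6.12% in the bin of shortest genes, with a median span of 1256 bases. In the bin of longest genes, with a median span of 107551 bases, it was 76.6%. Span was taken from the table's loci, which new models may have lengthened, so part of this trend may come from the new models themselves.

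Outside loci that join several genes, the most new models were listed for Plec, the gene of the cytoskeletal linker plectin, with 25 beside 21 annotated models (chromosome 15, 76170974 to 76232570, as the table gives loci, with no build named). Art3 followed with 20, the adhesion receptor gene Adgrl3 with 19, and the calcium channel gene Cacna1c and Ggt1 with 17 each. Ank3, which encodes the membrane scaffold ankyrin-G, and Ktn1 had 16 each, Pcdh15 had 15, Acin1, Clasp1 and the hexokinase gene Hk1 had 14 each, and Anks1b had 13. All 19 new models of Adgrl3 and all 14 of Clasp1 were longer than the longest annotated model of their gene, whereas none of the 25 of Plec, 16 of Ktn1, 14 of Acin1 or 13 of Anks1b was.

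Genes of hair cell identity and of the hair cell synapse carried new models in 22 of 29 cases (75.9%, 95% exact interval 56.5 to 89.7%), against 59.7% expected for genes of the same span and number of annotated models. The list had an exact p of 0.016 and an adjusted p of 0.19, so it did not pass the threshold. Expression was not matched, here or for the lists below. Its excess of 16.2 percentage points was 3.55 points when only new models longer than any annotated one counted and 7.73 points against the genes of the other lists. Ikzf2, a transcription factor of outer hair cells, had 7 new models beside 7 annotated, and Dnm3 had 6 beside 4. Myo6, an unconventional myosin, had 4 beside 6, and Otof, which encodes the synaptic calcium sensor otoferlin, had 4 beside 4. The 2 new models of Myo7a, a myosin of the hair bundle (chromosome 7, 98049864 to 98119524), reached 8476 bases against 7506 annotated. Slc26a5, the gene of the outer hair cell motor protein prestin, had 2 new models, and the transcription factor genes Gfi1 and Pou4f3 had 3 and 1. No new model was listed for Atoh1, the transcription factor that starts hair cell differentiation, whose only annotated model has 2088 bases (chromosome 6, 64729146 to 64731233). That model fills its whole locus and so has no intron, and number of exons was not matched.

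Among genes of the hair bundle and of mechanotransduction, 25 of 31 had a new model (80.6%, 95% exact interval 62.5 to 92.5%), against 66.2% expected. The exact p was 0.053 and the adjusted p 0.29. Pcdh15, which encodes a protein of the tip link that gates the transduction channel, had 15 new models beside 29 annotated (chromosome 10, 73821867 to 74649737). Espn, the gene of the actin-bundling protein espin, had 13 beside 14 annotated, and Eps8, an actin regulator at stereocilia tips, had 6 beside 7. Ptprq, a receptor phosphatase of the hair bundle, had 5 new models beside 1 annotated, and the longest reached 10171 bases against 7393 (chromosome 10, 107514410 to 107720064).

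Supporting cell and prosensory genes carried new models in 19 of 32 cases (59.4%, 95% exact interval 40.6 to 76.3%), against 44.3% expected, with an exact p of 0.038 and an adjusted p of 0.28. Counting only new models longer than any annotated one, this list lay on the other side of its expectation, at -6.48 percentage points against 15.1 points and without passing the threshold. Its excess was 7.29 points against the genes of the other lists and 8.04 points with strata of annotated length. Cd44, a hyaluronan receptor, had 8 new models beside 8 annotated. Prss23 had 4 beside 1, and Eya1, a transcriptional co-activator of otic development, had 4 beside 8. Lgr5, a receptor of R-spondins found on supporting cells with progenitor capacity, had 2 beside 3. Sox2, Jag1, Hes5 and Hey1, which act in the prosensory domain and in Notch signalling, had none listed, and Hes1 had 1. The only annotated model of Sox2 fills its locus without an intron. Among the other fixed names, the proliferation marker Mki67 had 5, the p53 target Cdkn1a and the heme oxygenase gene Hmox1 had 1 each, and the stress-induced Atf3 and Ddit3 had none listed. In all, 10 of the 17 fixed names had a new model.

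Of the 35 lists, 0 passed the adjusted threshold in the stratified exact test, and 5 had an unadjusted exact p under 0.05. Besides the hair cell and supporting cell lists, these were the mitochondrial ribosome with 21 of 35 genes (60.0% against 42.1% expected, exact p = 0.011), the cytosolic ribosome with 17 of 33 (51.5% against 35.2%, exact p = 0.014) and cartilage and bone with 8 of 25 (32.0% against 49.0%, exact p = 0.040). Their adjusted p values in the same exact test were 0.19, 0.19 and 0.28. Counting genes with at least 2 new models, the mitochondrial ribosome list turned from 17.9 to -11.5 percentage points from its expectation and the cartilage and bone list moved from -17.0 to 0.157 points. The cytosolic ribosome list kept its side in the 8 other settings that moved any list, at 4.72 points or more. Fisher's exact test without strata called 4 lists at adjusted p values under 0.05. The hair cell and hair bundle lists lay above all genes, and the lists of neutrophil, mast and lymphoid cells and of mitochondrially encoded genes lay below, at -38.1 and -46.8 percentage points. Against matched genes these deficits were -13.9 and -8.50 points, and -2.18 points for the 8 mitochondrially encoded genes left without joined loci.

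**Figure D1:**
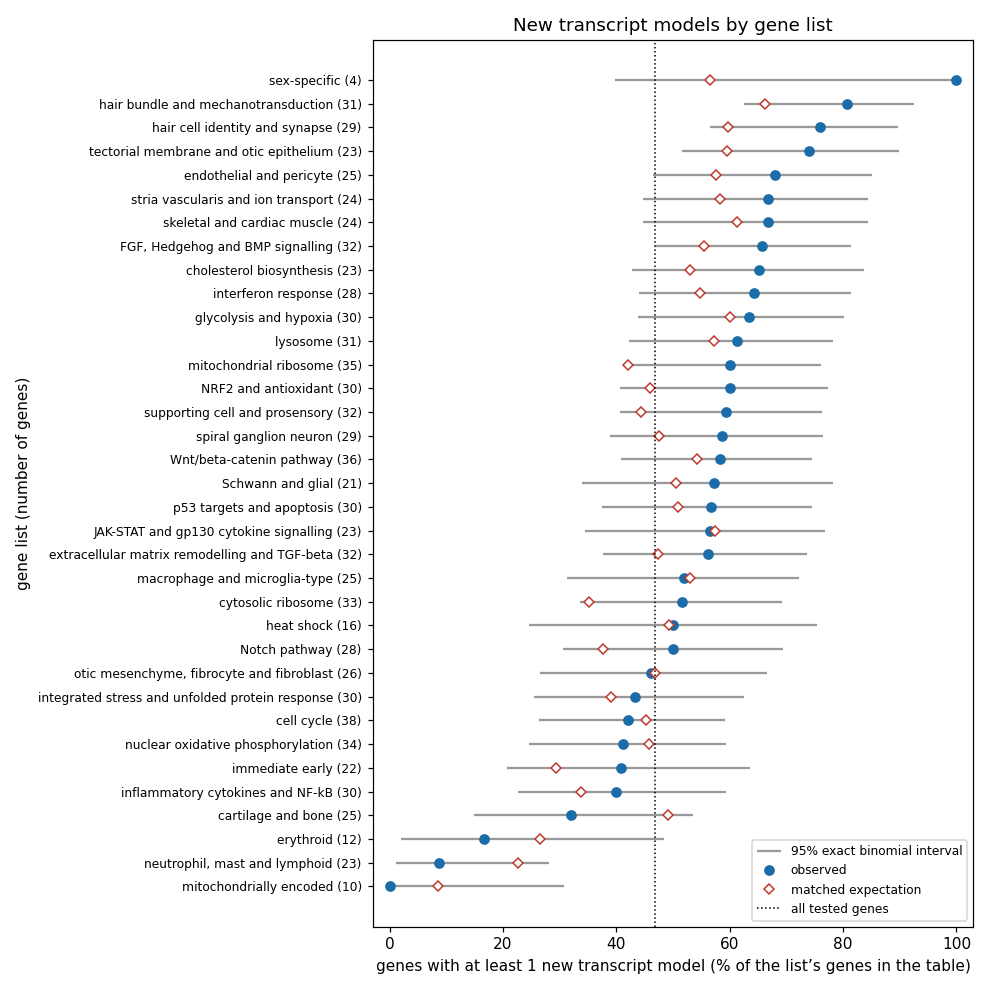
Percent of each list's genes with at least 1 new transcript model (x axis, filled circles, with 95% exact binomial intervals as grey lines) for the 35 gene lists (y axis, with the number of genes), beside the percent expected from genes of the same span and number of annotated models (open diamonds) and the percent over all tested genes (dotted line, 46.8%). The hair bundle list lies at 80.6% with a matched expectation of 66.2%, and the hair cell list at 75.9% with 59.7%.

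Tectorial membrane and otic epithelium genes had new models in 17 of 23 cases (73.9% against 59.6% expected), among them the splicing regulator Esrp1 with 4, of up to 6046 bases against 3864 annotated. The Notch list had 14 of 28 (50.0% against 37.6%), led by Numb with 6, the Wnt list 21 of 36 (58.3% against 54.3%), led by Tcf7l2 with 7, and the FGF, Hedgehog and BMP list 21 of 32 (65.6% against 55.5%). Cell cycle genes had 16 of 38 (42.1% against 45.3%). None of these 5 lists passed the adjusted threshold. The Notch list lay at -3.41 percentage points with at least 2 new models, against 12.4 points, and the Wnt list changed sides in 3 of these 8 settings, down to -2.71 points. The other lists of these 5 kept their side in all 8, with ranges of 9.61 to 27.1 points for the tectorial membrane list, 6.45 to 18.8 for the FGF, Hedgehog and BMP list and -11.8 to -2.03 for the cell cycle list.

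The 412 new genes had a median span of 5930 bases, and 300 of them had a single model. On the same strand, 287 (69.7%, 95% exact interval 65.0 to 74.1%) overlapped a non-coding gene or pseudogene of M21, 47 (11.4%) overlapped only a protein-coding gene, 16 (3.88%) overlapped genes of the opposite strand only and 62 (15.0%) overlapped no gene. Among the 287, the reference gene with the longest overlap was a lincRNA in 125 cases, a processed transcript in 76, an antisense transcript in 32 and a pseudogene in 33. The new gene with the most models, 8 of up to 8639 bases, lay on Miat (chromosome 5, 112213224 to 112228859). Others lay on H19, an imprinted non-coding RNA (chromosome 7, 142575519 to 142578129), on Neat1, the RNA scaffold of paraspeckles, on Pvt1, on the microRNA host genes Mir17hg and Mir22hg, on Mirg, on Sox2ot, the non-coding gene around Sox2, and on small nucleolar RNA host genes such as Snhg1, Snhg5 and Snhg12. Of the 47 on protein-coding genes, 9 lay on a gene matched by symbol to an Ensembl identifier of the table and 38 did not. Among the 38, 4 lay within Syne1, which encodes a nuclear envelope protein, and 3 within Naaladl2.

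**Figure D2:**
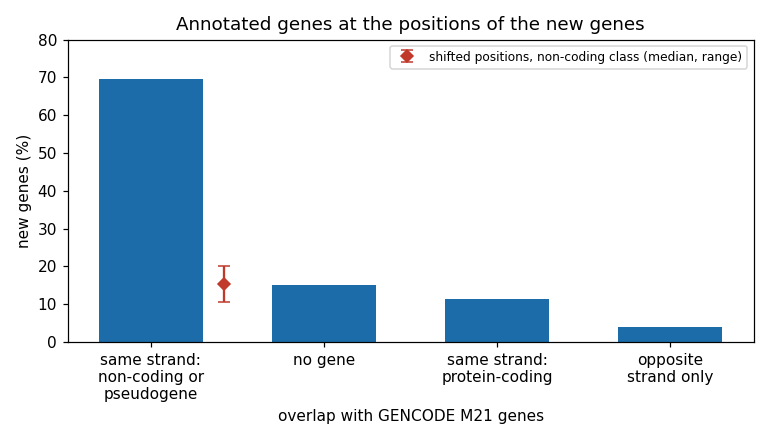
Percent of the 412 new genes (y axis, bars) by their overlap with GENCODE M21 genes (x axis). The diamond beside the first bar is the median of 1000 sets of shifted positions for that class, 15.3%, and its whiskers are their range, 10.4 to 20.2%, below the 69.7% of the new genes.

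In 362 Ensembl genes (1.67%), the identifier also held annotated transcripts of another gene, 918 transcripts of 487 genes in total. Fgfr2, a fibroblast growth factor receptor with 28 new models, the most of any gene, held transcripts of Ctbp2, which encodes the synaptic ribbon protein ribeye (M21 chromosome 7, 132987563 to 133124354). Pcp4 was listed under Igsf5, Id1, an inhibitor of basic helix-loop-helix factors, under H13, the heat shock gene Hspa1a under Hspa1b, the lysosomal channel gene Mcoln1 under Pnpla6, the sterol reductase gene Tm7sf2 under Zfpl1, and the ribosomal protein gene Rpl23 under 1700001P01Rik. On the mitochondrial genome, mt-Atp6 and mt-Co3 were listed under mt-Atp8 and mt-Nd4l under mt-Nd4. New models and loci of such identifiers can belong to either gene.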

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

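All alternatives here were chosen after the table had been seen, because every alternative fixed beforehand concerned log2 ratios between the mouse libraries and was not run. No paired analysis was possible because no comparison between samples was made. Of 21665 genes, 5199 had at least 2 new models and 5775 had one longer than any annotated model, against 10139 with any new model, since both definitions ask for more. Leaving out joined loci or sequences outside the main chromosomes kept this count within 1.5 times. Counting unnamed models moved neither this count nor any list and says nothing about stability. Without strata, Fisher's exact test put the hair cell list 29.1 and the hair bundle list 33.8 percentage points above all genes, both past the adjusted threshold, against 16.2 and 14.5 points above matched genes, which did not pass. This alternative drops the matching on span and annotated models. No other setting took any list past the threshold. Directions were less stable: 21 of the 35 lists changed sides of their expectation in at least 1 of the 8 other settings, 14 with at least 2 new models and 11 with only longer models, and 14 lists kept their side in all 8. Against the genes of the other lists, the hair cell, hair bundle and supporting cell lists lay 7.73, 11.2 and 7.29 points above expectation. With only longer models the hair cell list lay at 3.55 and the supporting cell list at -6.48 points. The background of the other lists (8 lists turned) and Fisher's exact test without strata (5 lists turned) change the reference genes. Turns in these settings need not mean instability. The causes of the turns in the other settings were not tested. When the reference gene had to cover at least 50% of the new gene, 61.9% of new genes lay on a non-coding gene or pseudogene, against 69.7%, since this definition is stricter. With lists of 30 genes drawn at random from all genes, the unadjusted test called 31% of simulated lists at an odds ratio of 2. The adjusted threshold used for the lists is stricter and was not simulated, so in such random lists excesses of that size would mostly be missed. The tested lists hold 4 to 38 genes in other mixtures of strata, so the share missed in them is not known.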

Other observations

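The tests of the overlap of new genes with non-coding genes were chosen after that overlap had been seen, the comparison of same-strand joined pairs was added after the first values for such pairs had been seen, the count of hair bundle genes in joined loci replaced a percentile without such loci that this count had fixed in advance, and the rule for reading the hair bundle percentiles was changed after their values had been seen, as described with them.

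Several other lists fixed beforehand showed no excess over matched genes that passed the adjusted threshold of the exact test. Endothelial and pericyte genes had new models in 17 of 25 cases (68.0% against 57.6% expected), led by the transcription factor gene Erg with 10. Genes of skeletal and cardiac muscle had them in 16 of 24 (66.7% against 61.3%), led by the titin gene Ttn with 11, of stria vascularis and ion transport in 16 of 24 (66.7% against 58.2%), led by the potassium channel gene Kcnq1 with 6, and of spiral ganglion neurons in 17 of 29 (58.6% against 47.5%), led by Rbfox3 with 7. Schwann and glial genes had 12 of 21 (57.1% against 50.5%), with 6 each for Drp2 and the myelin gene Mbp. Macrophage genes had 13 of 25 (13.3 expected) and fibroblast and mesenchyme genes 12 of 26 (46.2% against 46.8%). With at least 2 new models, the endothelial list turned from 10.4 to -1.39 percentage points from its expectation, the muscle list from 5.35 to -9.06 and the Schwann and glial list from 6.69 to -3.49 (-19.6 when only longer models counted), and the stria list moved from 8.44 to 0.725. The spiral ganglion list turned from 11.1 to -7.54 points when only longer models counted, and the macrophage list changed sides in 2 of 8 settings, with a range of -10.4 to 5.20 points. The fibroblast and mesenchyme list ranged from -16.3 to -0.555 points.

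Among blood cell lists, 2 of 23 neutrophil, mast and lymphoid genes, Mpo and Cd3g, had a new model (8.70% against 22.6% expected, exact p = 0.076, adjusted p = 0.29), and 2 of 12 erythroid genes, Car1 and Hbb-bs (16.7% against 26.6%). The deficit of the first list was -13.9 percentage points and ranged over the 8 other settings from -38.1 without strata to -3.54 with at least 2 new models, and the erythroid list ranged from -30.1 to -9.36. In the cartilage and bone list Sox6 had the most new models, with 8. None was listed for the 10 mitochondrially encoded genes (8.50% expected), a deficit that ranged from -46.8 percentage points without strata to -1.86 with at least 2 new models. The annotated models of mt-Co1, mt-Co2 and mt-Cytb fill their loci without an intron, and number of exons was not matched. Immediate early genes had 9 of 22 (40.9% against 29.3%), where the single new model of the transcription factor gene Egr3 has 4352 bases against 1416 annotated. This list changed sides in 3 of 8 settings, from 11.6 percentage points to as low as -5.89. Antioxidant genes had 18 of 30 (60.0% against 45.9%), genes of cholesterol biosynthesis 15 of 23 (65.2% against 52.9%) and genes of the interferon response 18 of 28 (64.3% against 54.8%). Their excesses of 14.1, 12.3 and 9.44 percentage points were as low as 6.18, 2.96 and 2.31 in other settings. Together, 496 of the 901 listed genes had a new model (55.0% against 48.4% expected, exact p = 1.9e-07). These genes are not independent replicates, and the expectation was not matched on expression.

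Hair bundle genes carried new models more often than all genes. The joining of neighbouring genes under 1 identifier is argued against, since 0 of the 31 members lie in a joined locus. Span and number of annotated models stay open as the whole cause: the count lies at percentile 98.3 of matched lists, which is above the central 95% set as the bound beforehand, but 97.4% of matched lists lie strictly below it and the two-sided exact p is 0.053. That bound ignored ties, so the reading was changed from excluding this cause to leaving it open. Transcription in the cochlea is a further candidate explanation, since the listed genes together exceed their expectation. Against the genes of the other lists the percentile is 95.5, which went with this explanation as written beforehand. That comparison cannot decide, because the other lists are no measure of transcription in the cochlea. They include neutrophil, mast and lymphoid genes, of which 8.70% had a new model. Values summed over both libraries, which need no treatment label, were not used. The excess itself is not established, so this explanation is left open too, and no biological explanation was tested.

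Most new genes lay on same-strand genes that M21 already annotates as non-coding genes or pseudogenes, 33 of the 287 on pseudogenes. The share of 69.7% is above the highest of 1000 shifted sets, 20.2%, which argues against chance overlap. A candidate explanation is that the annotation used to name the models held few such genes, since 97.9% of the annotated models found in M21 are protein-coding there. On this reading the word new would say little about these genes. Whether new models of Ensembl genes match M21 transcripts was not tested, so the word may say little about them as well. Of the 38 new genes on protein-coding genes not matched by symbol, 0 overlapped a same-strand Ensembl gene of the table. At these positions the table thus lists no annotated gene on that strand either, and whether the reason is the same was not tested. That may follow from how genes were named new and how the 38 were picked, so it is no independent evidence. The explanation does not cover the 9 new genes on protein-coding genes matched in the table. Nor does it cover the 16 that overlap genes of the opposite strand only or the 62 that overlap no M21 gene. No biological explanation was tested.

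Of the 489 pairs of a gene and the identifier it was listed under, 80.4% lay on the same strand and overlapped or lay within 10 kb, against 21.2% of 5000 random pairs of neighbouring protein-coding genes. Among same-strand pairs alone the values are 82.0% and 39.9%. For most pairs, neighbouring genes joined into 1 locus during assembly or merging would give this, and which step did so was not tested. It does not cover pairs on opposite strands or far apart, such as Hbs1l under Gm9923, with a gap of 50940422 bases. Pairs are also not independent, since many share the host Pcdha11. No biological explanation, such as read-through transcription, was tested.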
